A study of Pseudomonas putida KT2440 with 12 samples.

How the data were processed

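RNA-seq of Pseudomonas putida KT2440 on solid and in liquid M9 citrate medium was represented by 12 libraries, 2 per medium and time point (6, 12 and 24 h). Per the labels' protocols, RNA was extracted with RNeasy kits and treated with a DNA-free kit, and libraries were made and sequenced at a research centre. Per the submitters' processing notes, FastQC, Bowtie2, HTSeq and DESeq2 were used upstream, and their versions, settings and the genome build are not given in the sources used here. Whether counting used strand is likewise not given in the sources used here, so overlapping and antisense genes are uncertain, as are tRNA and rRNA genes with near-identical copies.

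The deposited files are 3 comparison tables, 1 per time point, with 5786 features each, of which 5564 carry a protein identifier. Per the file headers, the authors give for each feature a mean normalised count over the 4 libraries (a signal, scaled by their size factors), a log2 fold change of solid over liquid medium with its standard error, a test statistic (a score), a p-value and an adjusted p-value. The small fold changes of features with few reads (median absolute log2 of 0.225 at mean counts under 1 at 6 h) show that the authors' log2 fold changes are shrunken towards 0. Deposited p-values equalled those of a two-sided normal test of the deposited statistic (largest difference 5.0e-08 at 12 h), and deposited adjusted p-values equalled Benjamini-Hochberg adjustment over the features that have one. Those number 5013, 5332 and 5224 at 6, 12 and 24 h, with lowest mean counts of 11.28, 4.11 and 4.43, and are the genes called tested. The tables hold no counts per library, so the edgeR test planned before the data were examined could not be used, and the authors' DESeq2 values took its place. Totals per library are not given in the sources used here, and normalised mean counts summed to 5852035, 5915823 and 6870869.7. The 22 rRNA features took 0.52%, 0.34% and 0.197% of those sums. Names came from the symbols and products in the tables, and an identifier (gene followed by a number) is printed where a table gives no symbol. The reference gene table at hand belongs to another assembly and was not used.

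Genes with an adjusted p under 0.05 are said to rise, fall or pass. Standard errors were taken as the ratio of fold change and statistic where the absolute log2 fold change was at least 0.2, and as deposited otherwise. Differences between time points were tested by a z-test of the difference of fold changes over the joint standard error, with Benjamini-Hochberg adjustment over the genes tested at both times. Gene lists, 29 of them, were fixed from symbols and product names before the data were examined, and 26 had at least 5 tested members. A list was compared with the other genes by rotating it along the order of gene identifiers, which keeps neighbouring members together (two-sided), and by 10000 random lists matched on mean count in 10 bins, the smallest p from which is 1.0e-04. Benjamini-Hochberg adjustment covered 78 list tests. Locus tags are not used in the tables, so list members defined by tag ranges alone were left out, and 20 of 25 panel genes were found by symbol. Bootstrap intervals used 2000 draws over genes, because values per library were not at hand, so they do not measure spread between libraries. Overlaps were set against independent lists by the product of the shares of genes that passed. The rotation test, the matched lists, the z-test and 7 further lists were chosen after the tables had been seen.

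Genes named in the text follow a rule fixed before the data were examined: for each time point the 10 largest and 10 smallest log2 fold changes among genes with an adjusted p under 0.05, a mean value of at least 10 in the higher medium and a product other than hypothetical protein, up to 4 members of each described list with the smallest adjusted p, and the panel genes. Its further condition that both libraries of a medium lie on the same side could not be checked. Of the 246 genes the rule gives, 100 are named, and 23 others are named as chosen after their values were seen. Rescaling set each medium's total of all mean counts, or of protein-coding ones, equal by a single factor. Such factors were computed from the mean counts and fold changes.

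Scripts were tested on simulated data with the tables' own standard errors and 200 changed genes. At each time point more genes passed in the data than were changed in the simulation, so the simulated threshold was stricter. Simulated changes were also not shrunken, so recovery need not equal that in the data. Of 100 genes changed by a log2 of 2, 93, 55 and 84 were recovered at 6, 12 and 24 h, with 4, 7 and 3 false calls. Differences of 2 between time points were recovered in 37, 36 and 50 of 100 genes for 12 against 6 h, 24 against 12 h and 24 against 6 h. The rotation test called 10 of 200 simulated lists without and 200 of 200 with a shift. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.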

Results

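RNA was sequenced from Pseudomonas putida KT2440, a soil bacterium widely used in biotechnology, grown in M9 mineral medium with 0.2% citrate as carbon source. The medium was either liquid or made solid with 1.5% agar, and cells were taken after 6, 12 and 24 h. Each of the 6 groups held 2 libraries that the series describes as biological replicates, so 12 libraries in all and 4 behind each comparison. The authors' deposited tables, 3 in number, list 5786 features each, with a mean normalised count over the 4 libraries and a log2 fold change of solid over liquid medium. Values of single libraries were not used here, so every error given with a gene is the authors' standard error (SE) of its fold change. The mean counts summed to 5852035 at 6 h, 5915823 at 12 h and 6870869.7 at 24 h. Small non-coding RNAs and the tmRNA took 48.6%, 68.2% and 74.5% of those sums. The median tested gene had a mean count of 137 at 6 h, 69.2 at 12 h and 76.9 at 24 h.

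The comparison at 6 h asks which transcripts differ between surface-grown and suspended cells at the earliest time point. Genes of peroxide defence were among those that rose most on solid medium. In the authors' deposited table, katA, the main catalase, was 45.3-fold higher (log2 5.50, SE 0.263, adjusted p 3.0e-93). The same deposited table put ahpC, a peroxiredoxin that reduces organic peroxides, 32.9-fold higher (log2 5.04, SE 0.258) and trxB, the thioredoxin reductase, 24.3-fold higher (log2 4.60, SE 0.330). Of 17 tested oxidative stress genes, 8 rose and 2 fell, over all genes tested as well as adjusted over the list alone. Those that rose included ahpF and trxA, with log2 fold changes of 2.57 and 2.55 in the authors' deposited table. The manganese-type superoxide dismutase gene sodA went the other way, with -5.71 (SE 0.385) in the authors' deposited table. Other steep increases in the authors' deposited table were those of gene4034, from a family of oxygen-independent haem synthesis enzymes (5.21, SE 0.326), of syrB, a syringomycin synthesis homologue (3.84, SE 0.275), of an arylesterase (gene5609, 3.73), of an OsmY-like protein (gene5027, 3.62) and of gene1375, a DUF328 family protein related to the peroxide stress protein YaaA (3.15, SE 0.291).

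Many iron acquisition genes were lower on solid medium at 6 h. Among 45 tested siderophore and iron uptake genes, 20 fell and 25 did not pass the test, with 23 lower when adjusted over the list alone, and the list median was -0.92. The receptor gene fpvA, which takes up ferric pyoverdine, was 24.8-fold lower in the authors' deposited table (log2 -4.63, SE 0.295, adjusted p 1.4e-52). Genes that energise such receptors fell too, with tonB and exbD both at -3.18 in the authors' deposited table. Sigma factor genes of iron uptake followed, fecI with -3.64 (SE 0.371) and pvdS, the activator of pyoverdine synthesis, with -2.13 (SE 0.322) in the authors' deposited table. The steepest decreases of all named genes were those of fumC-I, an iron-independent fumarase, at -5.97 (SE 0.323, adjusted p 5.2e-73), and of sodA in the same deposited table. Membrane sensors gene3812 and gene175 stood at -4.61 and -4.52, and the neighbouring two-component genes gene1748 and pfeS-II at -5.37 and -4.45, in the authors' deposited table.

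Many genes of translation and energy metabolism rose at 6 h. Of 53 tested ribosomal protein genes 46 rose and the rest did not pass the test, with 48 higher when adjusted over the list alone and a median of 1.21. The authors' deposited table gave 2.94 for rplU (SE 0.328, adjusted p 2.1e-17), 2.35 for rpsP and 2.27 for rplM. ATP synthase and NADH dehydrogenase I moved nearly as a block, with 21 of 22 genes higher (22 adjusted over the list alone) and a median of 1.68. Subunit genes nuoG and atpI reached 2.25 (SE 0.260) and 2.01 (SE 0.302) in the authors' deposited table. Of 16 terminal oxidase genes 4 rose, adjusted over the list alone as well, with a median of 0.10 and an adjusted rotation p of 0.902. In the TCA cycle and glyoxylate shunt, 14 of 24 genes rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 1.14. Citrate synthase gltA, isocitrate lyase aceA and dihydrolipoyl dehydrogenase lpdG stood at 2.27, 2.12 and 2.06 in the authors' deposited table, while malate dehydrogenase mdh, chosen after its values were seen, fell with fumC-I, by 1.06. Most citrate uptake genes rose too, though their list as a whole missed the threshold (adjusted rotation p 0.0926): opdH, a tricarboxylate porin gene, the citrate transporter gene citN, and the TctB and TctC genes (gene1508 and gene1509) had 1.92, 1.49, 1.60 and 1.53 in the authors' deposited table, and these were the 4 of 6 uptake genes past the test, adjusted over the list alone as well. Amino acid biosynthesis had 27 of 79 genes higher and 4 lower (31 and 5 adjusted over the list alone), with dapA-I of lysine synthesis at 2.08, aroQ-I of the shikimate route at 2.02 and proC of proline synthesis at 2.01 in the authors' deposited table. The stable RNA list, whose product terms also took in protein-coding genes of rRNA and tRNA modification, had 43 of 89 genes higher and 2 lower (46 and 2 adjusted over the list alone), with a median of 0.87. Split after its values were seen, it held 44 tested tRNA genes, of which 30 rose, and 42 protein-coding genes, of which 13 rose and 2 fell.

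Some genes of other catabolic routes fell at 6 h. Among 45 amino acid catabolism genes 18 fell and 6 rose (19 and 6 adjusted over the list alone), with a median of -0.33, and the list as a whole did not stand apart (adjusted rotation p 0.164). Arginine succinyltransferase pathway genes astD and astA-I stood at -2.38 (SE 0.266) and -2.10 (SE 0.269), and homogentisate dioxygenase hmgA of the tyrosine route at -1.96 (SE 0.283), in the authors' deposited table. The arginine deiminase genes arcA and arcB went up instead, with 1.28 and 1.15 in the authors' deposited table. Thiolase gene pcaF-I of the beta-ketoadipate pathway was 24.3-fold lower in the authors' deposited table (log2 -4.60, SE 0.332), and the arylsulfatase gene atsA, used to free sulfate, had -4.44 (SE 0.395).

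Many flagellar genes fell by small amounts at 6 h. Of 45 tested 31 fell and 14 did not pass the test, with 35 lower when adjusted over the list alone, a median of -0.76 and an adjusted rotation p of 0.0604 for the list. In chemotaxis 4 of 35 genes fell, adjusted over the list alone as well, and 31 did not pass, with gene5229 at -2.16 in the authors' deposited table and an adjusted rotation p of 0.0926. The export genes fliJ, fliI and flhB and the ring gene fliF stood at -1.60, -1.40, -1.18 and -0.99 in the authors' deposited table. Flagellin gene fliC, at -0.26 (SE 0.270, adjusted p 0.555) in the authors' deposited table, and the regulator gene fleQ, at -0.47 (adjusted p 0.150), did not pass the test. Enzymes of cyclic di-GMP, a second messenger of surface attachment, had 7 of 24 genes lower and a median of -0.48 (9 lower and 1 higher adjusted over the list alone). The diguanylate cyclase-type genes gene3548, gene402 and gene5302 fell most clearly, at -2.49, -2.06 and -1.50 in the authors' deposited table. Stress genes osmC and katE rose with 2.04 and 1.68 in the authors' deposited table, while rpoS, the stationary phase sigma factor gene (0.16, SE 0.200), and dps (0.45, SE 0.272) did not pass the test.

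Altogether 1172 of 5013 genes tested at 6 h passed, 710 higher and 462 lower on solid medium, and 809 of them differed at least 2-fold. Tested as wholes by rotation along the gene order, within a family of 78 tests over 26 lists, adjusted p was 0.00194 for the ribosomal protein, iron uptake and stable RNA lists, 0.00467 for ATP synthase with NADH dehydrogenase, 0.00566 for the TCA cycle, 0.00346 for amino acid biosynthesis and 0.0394 for cyclic di-GMP enzymes, while the lists of oxidative stress (0.0603), flagellum (0.0604), citrate uptake and chemotaxis (0.0926 each), amino acid catabolism (0.164), sulfur (0.207) and terminal oxidases (0.902) missed the threshold. Random lists matched on mean count, which do not keep neighbouring members together, put some of the latter apart. Their adjusted p was 6.5e-04 for flagellum, 0.00501 for citrate uptake, 0.0291 for oxidative stress and 0.0376 for chemotaxis. Amino acid catabolism (0.0636), sulfur (0.162) and terminal oxidases (0.847) missed the threshold by that test as well. In simulated data with the errors of this comparison, 33 of 100 genes changed by a log2 of 1 and 93 of 100 changed by 2 were recovered.

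**Figure D1:**
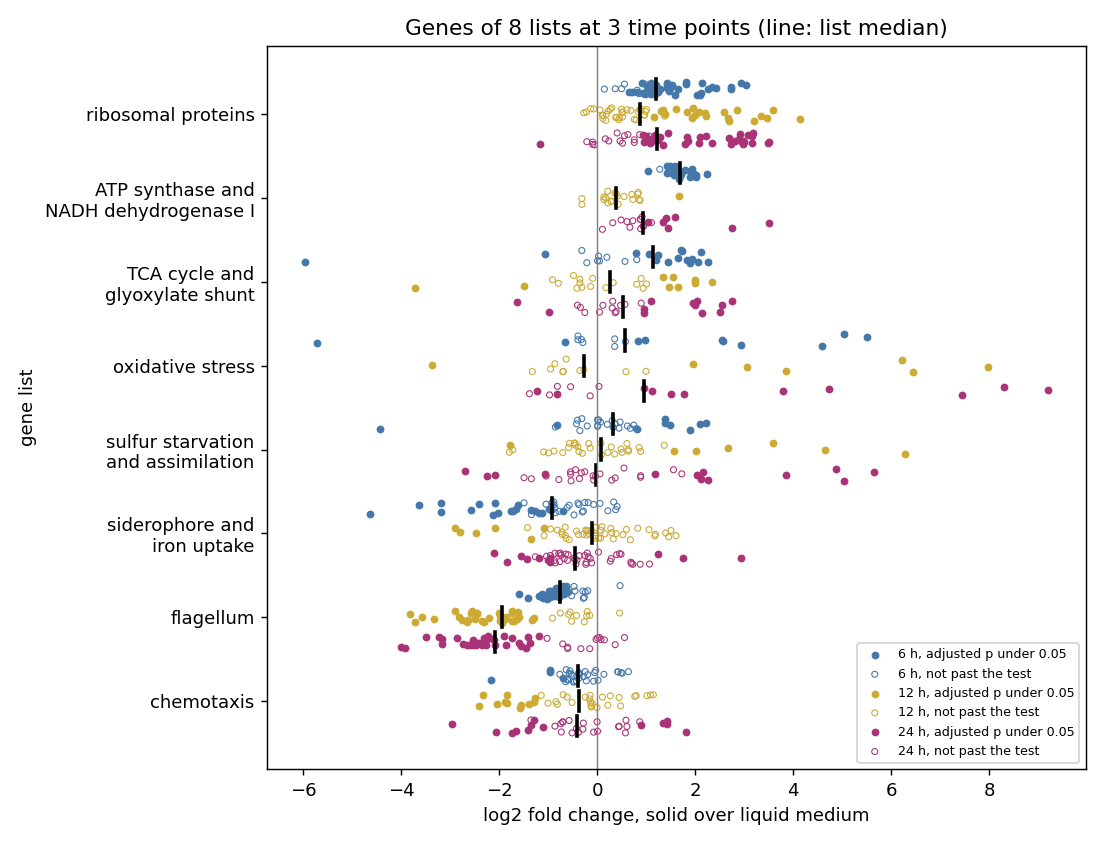
Log2 fold changes (solid over liquid medium, x axis) of the tested members of 8 gene lists (y axis) at 6, 12 and 24 h; filled points passed an adjusted p of 0.05, open points did not, and black lines mark list medians. Ribosomal protein medians lie between 0.88 and 1.21 and flagellar medians between -2.08 and -0.76, and both keep their direction when rescaled to all reads, whereas at 24 h the chemotaxis and iron uptake medians turn from -0.40 and -0.44 to 0.54 and 0.50 under that scaling.

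At 12 h the question was whether the early pattern lasted, and flagellar genes were prominent among those that fell. Of 45 flagellar genes 34 fell, adjusted over the list alone as well, and the median was -1.94 (-1.56 when rescaled to all reads). The hook gene flgE was 14.1-fold lower in the authors' deposited table (log2 -3.82, SE 0.423, adjusted p 5.2e-17), followed by flgD (-3.72), flgC (-3.57) and flgB (-3.33) of the rod and hook. Sigma factor gene fliA, which drives late flagellar genes, fell to -1.95 (SE 0.388) in the authors' deposited table, and fliC again did not pass (-0.26, SE 0.412). In chemotaxis 11 of 36 genes fell (13 adjusted over the list alone), among them the signalling genes cheZ and cheY with -1.84 and -1.56 and the receptor genes gene5229 and gene5364 with -2.41 and -2.33 in the authors' deposited table. The chemotaxis median of -0.38 rose to 0.00 when rescaled to all reads. Of 24 cyclic di-GMP enzyme genes 7 fell and 2 rose (8 and 2 adjusted over the list alone), with gene5302 at -2.13 against gene237 at 1.50 and gene871 at 1.79 in the authors' deposited table.

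Peroxide genes kept steep increases at 12 h, and a few sulfur genes had steep increases at that time. The authors' deposited table put katA 252-fold higher (log2 7.98, SE 0.385, adjusted p 9.2e-92), ahpC 87.4-fold (6.45, SE 0.424), trxB 75.1-fold (6.23, SE 0.440) and gene1375 47.5-fold (5.57, SE 0.443). Among 17 oxidative stress genes 6 rose and 1 fell (6 and 3 adjusted over the list alone), so that the list's mean of 1.29 and its median of -0.27 differed in sign, the median becoming 0.11 when rescaled to all reads. The sulfonate desulfuration gene ssuE was 77.7-fold higher in the authors' deposited table (log2 6.28, SE 0.487, adjusted p 6.5e-35). Sulfate activation gene cysD, taurine uptake gene tauA and sulfate-binding protein gene sbp-II stood at 4.66, 3.60 and 2.67 in the authors' deposited table, yet only 6 of 36 sulfur genes rose and 1 fell, with a median of 0.08, against 7 and 2 of 30 at 6 h with a median of 0.32, over all genes tested as well as adjusted over the list alone. Further steep increases in the authors' deposited table were the lipoprotein gene plpB at 5.49 (SE 0.544), the metal transporter gene gene1940 at 4.86 (SE 0.426) and a CBS domain gene, gene387, at 4.80 (SE 0.604).

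Translation genes were higher at 12 h as well, while few genes of the respiratory complexes passed the test. Of 54 ribosomal protein genes 21 rose, adjusted over the list alone as well, with a median of 0.88. The authors' deposited table gave 3.47 for rpsU (SE 0.499), 3.35 for rplU and 3.20 for rpsJ. In the stable RNA list 39 of 100 genes rose and 2 fell (44 and 3 adjusted over the list alone), with a median of 1.19. Its 53 tRNA genes had 30 higher, and its 44 protein-coding genes 9 higher and 2 lower. Only atpI, at 1.68 (SE 0.482) in the authors' deposited table, rose among 21 genes of ATP synthase and NADH dehydrogenase, whose median was 0.39. Among terminal oxidases cyoA of the cytochrome bo oxidase rose with 3.85 (SE 0.506) in the authors' deposited table, whereas ccoO-II of a high-affinity cbb3 oxidase fell with -2.08 (SE 0.485). That list had 1 gene higher and 4 lower of 15 (3 and 7 adjusted over the list alone), with a median of 0.12 and a mean of -0.07. The TCA list had 7 genes higher and 2 lower of 24, adjusted over the list alone as well, with idh, isocitrate dehydrogenase, at 2.34 and acnB, aconitase, at 1.65 in the authors' deposited table.

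Among genes of potassium and iron uptake, several fell at 12 h. The kdp genes of a potassium pump induced by low potassium fell, with kdpB at -3.35 (SE 0.503), kdpF at -3.11 and kdpA at -2.84 in the authors' deposited table, and trehalose and glycogen gene glgE rose with 2.11 (SE 0.473). Their osmoadaptation list had 5 genes higher and 8 lower of 45 (6 and 9 adjusted over the list alone), with a median of 0.07 and a mean of -0.13. A gamma-aminobutyrate transporter gene, gene4684, fell with -3.54 (SE 0.457) in the authors' deposited table. In iron uptake 6 of 49 genes fell (4 adjusted over the list alone), with exbD, fpvA and fecI at -2.90, -2.80 and -2.48 in the authors' deposited table, and the list, which did not stand apart (adjusted rotation p 0.674), had a median of -0.11 that became 0.27 when rescaled to all reads. fumC-I and sodA remained lower, with -3.72 (SE 0.610) and -3.36 (SE 0.732) in the authors' deposited table. The phasin-type gene gene5351, which coats polyhydroxyalkanoate granules, fell with -1.75 (SE 0.448) in the authors' deposited table and was the gene past the test among 4 of that storage polymer, whereas each of the 4 was lower when adjusted over the list alone.

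In total 843 of 5332 genes passed at 12 h, 526 higher and 317 lower, all 843 at least 2-fold. Rescaling to all reads or to protein-coding reads shifted every fold change by 0.38 or 0.27 and changed the split to 808 higher and 146 lower or to 710 and 172. The ribosomal protein (adjusted rotation p 0.0268), flagellar (0.00194), cyclic di-GMP (0.0313) and stable RNA (0.00194) lists stood apart from the other genes. Chemotaxis (0.135), ATP synthase with NADH dehydrogenase and oxidative stress (0.508 each), the TCA cycle (0.534), iron uptake (0.674), sulfur and terminal oxidases (0.915 each) and osmoadaptation (0.925) did not. Recovery in simulated data was 8 of 100 genes changed by a log2 of 1 and 55 of 100 changed by 2.

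**Figure D2:**
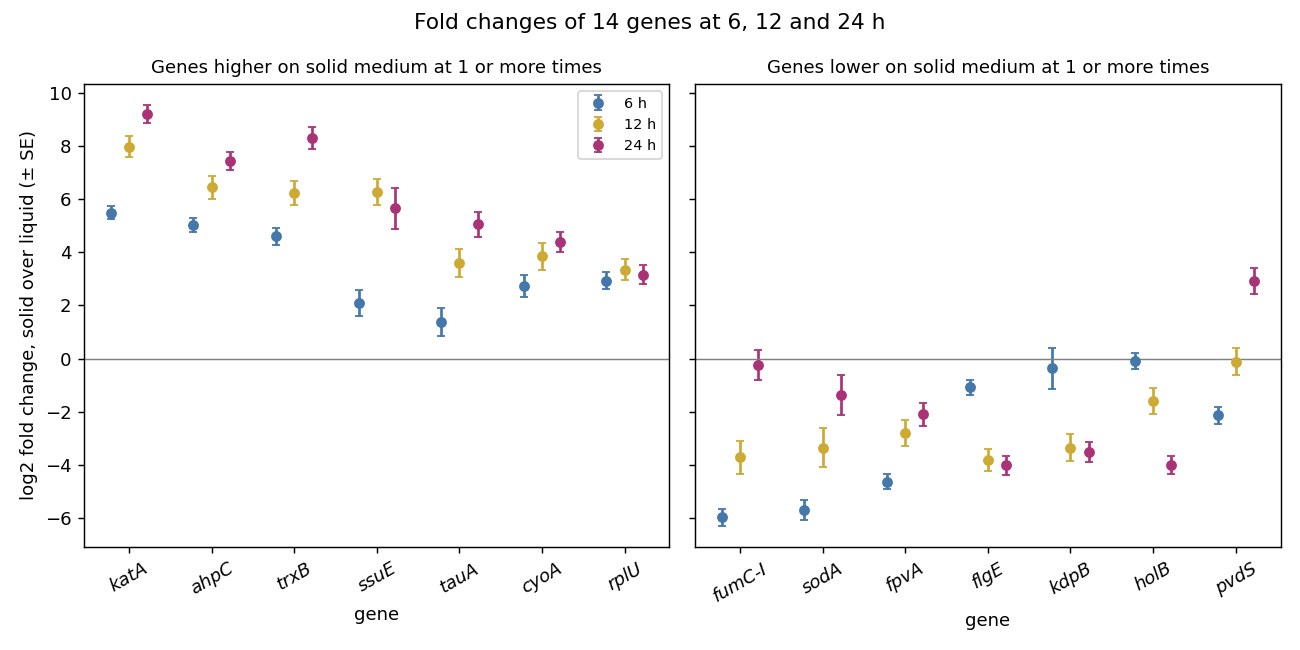
Log2 fold changes (solid over liquid medium, y axis) with standard errors as bars for 14 genes (x axis) at 6, 12 and 24 h, from the authors' deposited table; kdpB had no adjusted p at 6 h. The catalase gene katA goes from 5.50 to 9.21 and the hook gene flgE from -1.08 to -4.01, while pvdS passes from -2.13 to 2.93.

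The comparison at 24 h covers the latest time point, and katA, trxB and ahpC had their highest folds there. In the authors' deposited table katA was 592-fold higher (log2 9.21, SE 0.350, adjusted p 1.8e-148), trxB 315-fold (8.30, SE 0.414), ahpC 174-fold (7.44, SE 0.352) and gene1375 93.1-fold (6.54, SE 0.383). Of 17 oxidative stress genes 9 rose and 2 fell (9 and 4 adjusted over the list alone), with a median of 0.96. Some sulfur acquisition genes were again higher, with ssuE at 5.66 (SE 0.764), tauA at 5.05 (SE 0.480) and sbp-II at 4.88 (SE 0.385) in the authors' deposited table. The sulfur list had 9 genes higher and 4 lower of 35, adjusted over the list alone as well, with a median of -0.03, a mean of 0.56 and a median of 0.91 when rescaled to all reads. A DszC-type monooxygenase gene of organic sulfur use, gene245, stood at 6.19 (SE 0.785), plpB at 6.10 (SE 0.760) and gene1940 at 5.19 (SE 0.321) in the authors' deposited table.

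Many flagellar genes were lower at 24 h too, and few exopolysaccharide genes passed the test. Of 45 flagellar genes 32 fell (35 adjusted over the list alone), with a median of -2.08, which became -1.14 when rescaled to all reads. The authors' deposited table gave -4.01 for flgE (SE 0.357, adjusted p 6.0e-27), -3.91 for flgD, -3.50 for flgC and -2.12 for fliA. In chemotaxis 8 of 34 genes fell and 5 rose (10 and 5 adjusted over the list alone), with gene5229 at -2.97 in the authors' deposited table and a list median of -0.40 that turned to 0.54 when rescaled to all reads. Among cyclic di-GMP enzymes 5 of 24 fell and 2 rose, adjusted over the list alone as well, with gene5302 at -1.73 and gene237 at 2.31 in the authors' deposited table, and the median of -0.44 turned to 0.50 under the same rescaling. Phosphomannomutase gene algC, which supplies sugar precursors of exopolysaccharide, rose with 1.77 (SE 0.343) in the authors' deposited table and was the gene past the test among 14 of the exopolysaccharide and adhesin list, over all genes and adjusted over the list alone. The members found for that list were alginate and cellulose genes, with no adhesin gene among them. Cellulose synthase gene bcsA did not pass at any time, with -0.79, 0.50 and -0.01 in the authors' deposited table.

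Ribosomal protein genes were higher at 24 h in 35 of 54 cases and lower in 1 (39 and 1 adjusted over the list alone), with a median of 1.21. The authors' deposited table gave 3.16 for rplU (SE 0.347), 3.16 for rpsP and 2.82 for rpsF, against -1.17 (SE 0.370) for rpsO, chosen after its values were seen, which did not pass when rescaled to all reads (-0.23). In the stable RNA list 57 of 102 genes rose and 3 fell (60 and 3 adjusted over the list alone), with tRNA-Thr gene gene480 at 4.14 (SE 0.525) in the authors' deposited table and a median of 1.46. Among them 37 of 56 tRNA genes rose, and of 43 protein-coding genes 20 rose and 3 fell. Reads of near-identical tRNA copies cannot be assigned with certainty. In energy metabolism 7 of 20 genes of ATP synthase and NADH dehydrogenase rose, adjusted over the list alone as well, led by atpI and atpB with 3.50 and 2.76 in the authors' deposited table. The TCA list had 10 genes higher and 2 lower of 24, adjusted over the list alone as well, with gltA, sdhC and acnB at 2.76, 2.56 and 2.51 in the authors' deposited table. Of 6 citrate uptake genes 3 rose (4 adjusted over the list alone), opdH, citN and gene1509, at 3.84 (SE 0.354), 2.78 (SE 0.377) and 1.47 in the authors' deposited table. Oxidase gene cyoA reached 4.39 (SE 0.365) and glutamine synthetase gene glnA 3.39 (SE 0.333) in the authors' deposited table.

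Stress and nutrient genes went both ways at 24 h. The sigma factor gene rpoS was lower at -1.11 (SE 0.301) in the authors' deposited table, while osmC and katE, which are commonly under its control, were higher at 2.41 and 2.28. When rescaled to all reads, rpoS no longer passed (-0.17). Small non-coding RNAs and the tmRNA held 74.5% of the 24 h mean counts and so largely set that factor. Rescaling to protein-coding reads shifted 24 h values by only 0.02. Of 20 stationary phase and general stress genes 3 rose and 7 fell, adjusted over the list alone as well, with a median of -0.06 that became 0.88 when rescaled to all reads. Ribosome hibernation genes hpf and rmf, chosen after their values were seen, were among those that fell, at -1.15 and -1.04 in the authors' deposited table, and did not pass under that rescaling (-0.21 and -0.10). The kdp genes stayed lower, with kdpC at -4.54 (SE 0.514), kdpF at -3.59, kdpB at -3.52 and kdpA at -3.45 in the authors' deposited table, whereas glgE rose with 2.46 (SE 0.358). Their osmoadaptation list split into 12 genes higher and 12 lower of 45 (12 and 13 adjusted over the list alone), with a median of -0.18 that turned to 0.76 when rescaled to all reads. In iron uptake 8 of 48 genes fell and 3 rose (5 and 3 adjusted over the list alone), with a median of -0.44 that turned to 0.50 under that rescaling. Those that rose were pvdS at 2.93 (SE 0.486), the receptor gene gene4403 at 1.75 and exbB at 1.24 in the authors' deposited table, while fpvA stayed lower at -2.10 (SE 0.446). Further steep decreases were those of holB, a DNA polymerase subunit gene, at -4.00 (SE 0.344), its neighbour gene2088, a nucleotide kinase gene, at -3.84, and the dehydroquinate dehydratase gene aroQ-II at -3.83 (SE 0.853) in the authors' deposited table.

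At 24 h 1593 of 5224 genes passed, 939 higher and 654 lower, 1426 of them at least 2-fold. Rescaling to all reads shifted every fold change by 0.94 and changed the split to 2332 higher and 115 lower, whereas protein-coding reads gave 959 and 622. The flagellar, ribosomal protein and stable RNA lists (adjusted rotation p 0.00194 each) and the oxidative stress list (0.0299) stood apart from other genes. Iron and citrate uptake (0.135 each), ATP synthase with NADH dehydrogenase (0.143), chemotaxis and cyclic di-GMP (0.197 each), the TCA cycle (0.208), terminal oxidases (0.397), exopolysaccharides with adhesins (0.550), osmoadaptation (0.648), stationary phase (0.936) and sulfur (0.949) did not. Simulated recovery was 17 of 100 genes changed by a log2 of 1 and 84 of 100 changed by 2.

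**Figure D3:**
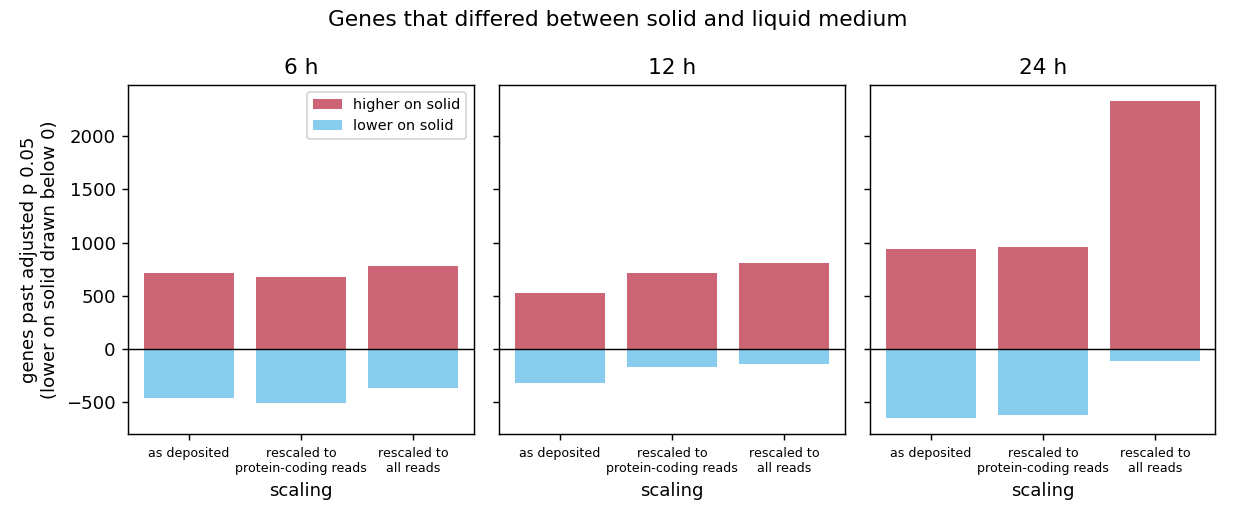
Numbers of genes past an adjusted p of 0.05 (y axis; genes lower on solid medium are drawn below 0) at 6, 12 and 24 h under 3 scalings (x axis). At 24 h the higher and lower genes number 939 and 654 as deposited, 959 and 622 when rescaled to protein-coding reads and 2332 and 115 when rescaled to all reads.

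The effects of solid medium were then compared between time points, to ask which genes responded differently early and late. Some peroxide and sulfur genes gained from 6 to 24 h: differences between log2 fold changes in the authors' deposited table were 3.71 for katA (SE 0.438, adjusted p 1.3e-14), 3.70 for trxB (SE 0.530), 4.07 for sbp-II (SE 0.497) and 3.67 for tauA (SE 0.717). The solid over liquid ratios of some iron genes moved up towards or past equality, with differences of 5.72 for fumC-I (SE 0.652), 5.06 for pvdS (SE 0.583) and 3.81 for exbB (SE 0.415) between values in the authors' deposited table. For fumC-I the mean count over both media fell from 1229 at 6 h to 26.5 at 24 h, so its ratio closed as its level fell. The hook gene flgE had moved down by 12 h, with a difference of -2.74 (SE 0.504) between values in the authors' deposited table, and the difference to 24 h was -2.93 (SE 0.450). Some catabolic genes that were lower than in liquid medium at 6 h were no longer so at 24 h, with differences of 4.51 for pcaF-I (SE 0.698), 3.51 for hmgA (SE 0.432) and 2.41 for astD (SE 0.511) in the authors' deposited table. The mean count of pcaF-I over both media fell from 297 to 19.2 between those times, so its ratio closed at low counts. Early increases were lost for syrB, gene4034 and proC, whose values in the authors' deposited table differed from 6 to 24 h by -4.14 (SE 0.647), -4.78 (SE 0.771) and -2.53 (SE 0.413). The arc genes changed direction between 6 and 12 h, arcA from 1.28 to -1.56 in the authors' deposited table, a difference of -2.84 (SE 0.528, adjusted p 1.4e-05).

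Effects differed between 6 and 24 h for 319 of 4963 genes, 192 towards higher and 127 towards lower values on solid medium. Between 6 and 12 h 178 of 4986 genes differed (79 and 99), and between 12 and 24 h 33 of 5180 (25 and 8). These splits depended on scaling: rescaled to all reads, they became 1266 and 49 from 6 to 24 h, 131 and 59 from 6 to 12 h and 149 and 5 from 12 to 24 h, against 204 and 114, 131 and 59, and 17 and 12 when rescaled to protein-coding reads. Among 78 list tests, member effects shifted for the flagellar list by -1.07 to 12 h and -1.08 to 24 h, for iron uptake by 0.67 and 0.53, for ATP synthase and NADH dehydrogenase by -1.21 to 12 h, for oxidative stress by 0.77 to 24 h and for the stable RNA list, modification enzymes included, by 0.36 and 0.35. Rescaled to all reads, the flagellar shift to 24 h shrank to -0.21, while those of iron uptake, oxidative stress and stable RNA grew to 1.40, 1.64 and 1.22. Rescaled to protein-coding reads, the same shifts were -1.03, 0.58, 0.82 and 0.40. Small non-coding RNAs and the tmRNA held 74.5% of the 24 h mean counts and so largely set the all-reads factor. A joint test was made from the deposited fold changes and their standard errors, with time points taken as independent.

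Time points shared more of the genes that passed than independent lists would. Of the genes tested at all 3 times, 319 were higher at each, including katA, ahpC, trxB, cyoA, gltA, rplU and glgE, where independent lists would share 13.1. Those lower at each numbered 89 against 3.74, including flgE, fliI, fpvA, gene5302 and gene5229. Between 12 and 24 h 461 higher and 177 lower genes were shared (94.2 and 39.9 for independent lists), and between 6 and 12 h 330 and 132 (71.6 and 28.9). At 1 or more times 2211 genes passed. Across genes, fold changes correlated with Pearson's r of 0.620 (Spearman's rho 0.595) between 6 and 12 h, 0.765 (0.720) between 12 and 24 h and 0.626 (0.654) between 6 and 24 h, and genes are not independent replicates.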

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

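The tests of differences between time points and all tests of explanations, other than that of the 12 h standard errors, were chosen after the results had been seen. Results are listed here because the effect of solid medium differed between time points, by a z-test of the difference of the authors' deposited fold changes with Benjamini-Hochberg adjustment. That held for 178 genes between 6 and 12 h, 33 between 12 and 24 h and 319 between 6 and 24 h, and for 8 list differences: flagellum (-1.07 to 12 h, -1.08 to 24 h), siderophore and iron uptake (0.67, 0.53), ATP synthase and NADH dehydrogenase I (-1.21 to 12 h), oxidative stress (0.77 to 24 h) and the stable RNA list with its modification enzymes (0.36, 0.35). Of 123 genes named in the text 69 differed, and the values that follow are their 24 h minus 6 h differences of log2 fold changes from the authors' deposited tables, unless another pair of times is given.

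Peroxide and thiol genes moved up by 3.71 (katA), 3.70 (trxB), 3.39 (gene1375), 2.40 (ahpC), 2.17 (ahpF) and 1.24 (trxA). Some sulfur, metal and nitrogen uptake genes moved up by 4.07 (sbp-II), 3.95 (plpB), 3.67 (tauA), 3.56 (ssuE), 2.25 (gene1940), 1.85 (glnA) and 1.63 (cysD). Iron genes and their sensors moved up by 5.72 (fumC-I), 5.12 (gene1748), 5.06 (pvdS), 4.33 (sodA), 3.81 (exbB), 3.19 (pfeS-II), 2.67 (fecI), 2.53 (fpvA), 2.43 (gene175), 2.42 (tonB), 2.32 (exbD) and 2.28 (gene3812), and the bacterioferritin gene bfr-II moved by -2.02. Catabolic genes moved up by 4.72 (catB), 4.51 (pcaF-I), 3.76 (benA), 3.51 (hmgA), 3.10 (atsA), 3.08 (pcaJ), 2.93 (benB), 2.41 (astD) and 2.09 (astA-I). Such shifts are of the solid over liquid ratio and need not be gains on solid medium. Mean counts over both media fell from 6 to 24 h for benA (3042 to 38.4), catB (609 to 11.7), fumC-I (1229 to 26.5) and sodA (452 to 10.7). Smaller upward shifts were 1.97 (gene237), 1.92 (gene3548), 1.76 (aroQ-I), 1.66 (cyoA), 1.49 (atpI) and 1.29 (rpsF). For gene3548 this was an early decrease that narrowed, from -2.49 at 6 h to -0.57 at 24 h.

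Flagellar genes moved by -2.96 (flgD), -2.93 (flgE), -2.57 (flgC), -2.46 (flgB) and -1.24 (fliA), and adhesion genes by -1.47 (gene880) and -1.28 (gene184). Early increases were lost by -4.78 (gene4034), -4.14 (syrB), -3.41 (gene5027), -2.53 (proC) and -2.38 (gene2410). Late decreases amounted to -3.90 (holB), -3.60 (gene2088), -2.60 (rpsO), -2.40 (gene4684), -2.02 (CrcZ gene5016), -1.71 for both RsmY and RsmZ, -1.54 (hpf) and -1.27 (rpoS). Rescaling to all reads adds 0.87 to each difference from 6 to 24 h, and then fliA (-0.37), gene880 (-0.60), gene184 (-0.41), RsmY and RsmZ (-0.84 each), hpf (-0.67) and rpoS (-0.40) no longer passed. Between 6 and 12 h the differences were -3.99 (gene2407), -3.42 (gene5609), -2.84 (arcA), -2.72 (arcB), -1.98 (ccoO-II) and -1.88 (nuoG), and between 12 and 24 h -4.30 (gene387). Either rescaling adds 0.30 from 6 to 12 h, and gene5609 (-3.12), ccoO-II (-1.68) and nuoG (-1.58) then no longer passed. Of the 69 genes, 59 still differed in the same direction when rescaled to all reads and 66 when rescaled to protein-coding reads.

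Many ribosomal protein and tRNA genes were higher and many flagellar genes lower on solid medium at each time, although at 12 h 33 of 54 ribosomal protein and 23 of 53 tRNA genes did not pass and at 6 h the flagellar list missed the threshold (adjusted rotation p 0.0604). Scaling between media moves every gene alike and gives no gap. Ribosomal protein and flagellar medians lay 1.97 or more apart (95% bootstrap interval over genes at 6 h 1.86 to 2.27). A single factor therefore cannot by itself give that contrast, though it may have shifted either median. The lists were paired after their directions were seen, so the gap restates the pattern and its interval is no independent support. Favoured short transcripts could also raise the other small RNAs, but the ribosomal protein median lay 0.97 or more above theirs (interval at 12 h 0.58 to 1.41). Lengths were not used, and those RNAs include tmRNA, RNase P and CrcZ, so this does not decide the question for ribosomal protein genes. For tRNA genes the same bias cannot be told apart from a real increase. No other class as short as tRNA was set beside it (small RNA median at 24 h 0.19). Slower entry into stationary phase on solid medium is a possible explanation that stays open, since the stationary phase list did not stand apart at 24 h (adjusted rotation p 0.936) and growth was not measured.

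Iron uptake genes were lower and ferritin genes higher on solid medium at 6 h: the genes annotated as ferritin or bacterioferritin, chosen after their values were seen, all rose, with bfr-II at 3.14 (SE 0.332), bfr-I at 2.19 (SE 0.266) and gene5195 at 1.74 (SE 0.645) in the authors' deposited table, as did sodB, the iron-type superoxide dismutase gene, at 2.94 (SE 0.265). Scaling between media moves every gene alike. The iron uptake median lay apart from that of the other tested genes (difference -0.93, 95% bootstrap interval -1.30 to -0.72), which argues against scaling as the whole cause of that part. The smallest ferritin value lay 1.74 above the median of its other genes (lower 95% bound from that gene's SE 0.48). Under either rescaling 3 of 3 ferritin genes were still higher, but the rescalings moved 6 h values by only 0.07 and -0.03. Because the ferritin genes were chosen after their values were seen, their part is no independent evidence against scaling. Less iron limitation on solid medium may account for the whole pattern as a hypothesis. Both loci of PrrF, an RNA that iron represses, fell at 6 h, with -2.84 (gene4333, SE 0.698, mean count 14.2) and -1.57 (gene5003, SE 0.406) in the authors' deposited table. PrrF is a transcript that answers to iron like the pattern to be explained, so it is not independent support. Iron in the media was not measured, and at 24 h pvdS and exbB were higher while fpvA and gene5003 (-2.44) were lower. Each of the 3 ferritin genes was higher at 12 and 24 h as well (medians 1.66 and 1.27), so whether the idea extends to later times stays open.

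Fewer genes passed at 12 h (843) than at 24 h (1593). Larger standard errors at 12 h are a possible explanation. With each gene's 24 h standard error in place of its own, 1310 genes pass at 12 h, which closes 62.3% of the gap. In that swap the 12 h fold changes keep their own noise, so the count rises whatever the cause. With the 6 h standard errors 1761 genes pass at 12 h, more than at 24 h. The swap therefore cannot tell how much of the gap the standard errors account for. Median standard errors were 0.506 at 12 h and 0.425 at 24 h, and median absolute fold changes 0.60 and 0.67. Whether replicates were less alike at 12 h for technical or biological reasons was not tested.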

How the results depend on the processing

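All alternatives in this part other than the one without a filter on low values were chosen after the tables had been seen. With no filter 1128, 834 and 1570 genes passed at 6, 12 and 24 h. Counts moved by more than 1.5 times at an adjusted p under 0.01 (740 at 6 h, 511 at 12 h), which is stricter by construction, when 12 h fold changes took the standard errors of 6 h (1761) or 24 h (1310), smaller by construction, and when 24 h fold changes were rescaled to all reads (2447), which adds 0.94 to each. That rescaling also raised the genes whose effect differed to 1315 from 6 to 24 h and to 154 from 12 to 24 h. Random lists matched on mean count put 11 lists apart at 6 h and 8 at 24 h, against 7 and 4 by rotation, and 4 by either at 12 h. Apart by matching alone were flagellum, chemotaxis, citrate uptake and oxidative stress at 6 h. At 24 h these were iron uptake, citrate uptake, amino acid biosynthesis, and ATP synthase with NADH dehydrogenase. Leaving out non-coding features, a mean count of at least 50 or a fold of at least 2 kept the total counts within 1.5 times, although the fold limit left 564 higher and 245 lower genes at 6 h, against 710 and 462. The medians of lists that stood apart kept their sign under both rescalings, 15 of 15 each. Of 362 values of named genes, 22 lost and 13 gained significance when rescaled to all reads, 5 and 4 when rescaled to protein-coding reads, and 1 (sbp-II at 6 h) without a filter, with no called value changing sign.

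No paired analysis was possible because the tables hold comparisons and no values of single libraries. For the same reason the planned DESeq2 size factors, library-size scaling, DESeq2 test, fits of 4 libraries, replicate blocks, stable RNA removal before library sizes, leaving out each library, other pseudocounts and a set test with correlation between genes were not run, nor were contrasts between times within a medium. With 2 libraries per group and median mean counts of 137, 69.2 and 76.9, log2 changes of 1 were recovered in 33, 8 and 17 of 100 simulated genes at 6, 12 and 24 h.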

Other observations

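All tests in this part, its gene lists and those of its genes that the report does not name were chosen after the values had been seen. Many tRNA genes rose on solid medium. Of the tRNA genes tested, 30 of 44 rose at 6 h, 30 of 53 at 12 h and 37 of 56 at 24 h, with medians of 1.62, 2.02 and 2.08 (adjusted rotation p 6.0e-04 each, in a family of 18 tests over 6 added lists). Among the other small RNAs 5 rose and 3 fell of 32 at 6 h, 5 and 2 of 32 at 12 h and 3 and 9 of 33 at 24 h, and their list did not stand apart (medians 0.22, -0.09 and 0.19; adjusted rotation p 0.285, 0.661 and 0.621). Rescaled to all reads, the 12 h median became 0.29 and the 24 h median 1.13, with 10 higher and 4 lower at 24 h, so the late excess of decreases was absent under that scaling. These RNAs, tmRNA included, held 74.5% of the 24 h mean counts and so largely set that factor. The rescaling therefore cannot test their decrease. Rescaling to protein-coding reads shifted 24 h values by 0.02. Those that fell at 24 h included CrcZ (gene5016 at -2.48, SE 0.322, and gene3776 at -1.70, SE 0.291, in the authors' deposited table), an RNA that relieves catabolite repression, and RsmZ and RsmY (gene1721 at -1.92 and gene404 at -1.50), which titrate repressors of translation. The tmRNA, which rescues stalled ribosomes and held 42.5% of the mean counts at 24 h, stood at -1.19 (SE 0.351) in the authors' deposited table. When rescaled to all reads, a total that tmRNA itself helps to set, tmRNA and RsmY no longer passed, at -0.25 and -0.56.

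Aromatic catabolism and iron-type sensors formed a further early group. Of 27 benzoate and beta-ketoadipate genes 19 fell at 6 h, with a median of -2.63 (adjusted rotation p 6.0e-04), and benB, benA, catB and pcaJ stood at -3.92, -3.87, -3.69 and -4.04 in the authors' deposited table. At 12 h 0 of 26 passed by the authors' DESeq2 values (1 at an unadjusted p under 0.05), and at 24 h 6 fell and 1 rose of 25, with a median of -0.49 that turned to 0.45 when rescaled to all reads. Anti-sigma sensors and their sigma factors, which commonly control siderophore receptors, fell in 15 of 19 cases at 6 h (median -3.46) and in 10 of 22 at 12 h (-1.25), both with an adjusted rotation p of 6.0e-04, and went both ways at 24 h with 4 higher and 4 lower of 22. Pyoverdine genes, all of them also members of the iron uptake list described above, fell in 8 of 13 cases at 6 h, with a median of -1.27 (adjusted rotation p 0.0236). At 12 h 0 of 15 passed by the authors' DESeq2 values (0 at an unadjusted p under 0.05). At 24 h 4 fell and 1 rose of 15, and the list did not stand apart (adjusted rotation p 0.305).

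Some neighbouring genes moved as blocks. Runs of at least 5 features with adjacent identifiers that passed in 1 direction numbered 15 higher and 12 lower at 6 h, 3 and 7 at 12 h and 17 and 11 at 24 h. A run of 11 features around syrB, with a peptide synthetase and an efflux transporter, passed as higher at 6 h and not at 12 or 24 h (medians 2.48, -0.01 and -0.03). Of these features 7 differed between 6 and 12 h and 9 between 6 and 24 h. A sugar ABC transporter run of 6 features had a median of 1.25 at 6 h and of -2.76 at 12 h, and each of the 6 passed at both times in opposite directions and differed between them. Its binding protein gene gene2410 stood at 1.90 (SE 0.282) and -2.96 (SE 0.521) and its permease gene gene2407 at 1.05 and -2.94 in the authors' deposited table. A run of 8 features with holB and a recombinase gene fell at 24 h (median -3.27), from -0.69 at 6 h. Features of 1 run can share a transcript and are not independent.

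A pair of genes annotated for surface adhesion, picked by their values and not tested as a group, were lower at 12 and 24 h. The fixed list of exopolysaccharides and adhesins holds neither, and by the authors' DESeq2 values 0 of 21 genes passed at 12 h (3 at an unadjusted p under 0.05, 0 adjusted over the list alone) and 1 of 14 rose at 24 h (adjusted over the list alone as well). The authors' deposited table gave gene880 0.37 (SE 0.237) at 6 h, -1.74 (SE 0.476) at 12 h and -1.10 (SE 0.374) at 24 h, the last of which became -0.16 and no longer passed when rescaled to all reads. In the same deposited table gene184 had -0.68, -2.32 and -1.96, and the first of these did not pass when rescaled to all reads.

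A lower CrcZ level could mean stronger repression of amino acid catabolism on solid medium at 24 h. The list of amino acid catabolism genes had a median of -0.06 there (0.88 when rescaled to all reads; adjusted rotation p 0.925), with 4 genes higher and 6 lower of 46 (4 and 6 adjusted over the list alone), so the test left this open.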
